A study of Homo sapiens with 12 samples.

How the data were processed

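Total RNA from OVCAR8 and SKOV3 cells was sequenced in 12 libraries, 2 per group, after random-primed library preparation with a NEBNext Ultra II kit, per the labels' protocols. Whether the reads kept their strand is not stated, so overlapping and antisense genes are uncertain, as are near-identical copies. The submitters' processing notes name HISAT2 2.2.1, StringTie, DESeq2 and hg38, with no roles given, while the source column of the deposited files reads Cufflinks, so the program behind the values is not settled. Each deposited file held, per the file headers, an FPKM (fragments per kilobase of transcript, scaled to the mapped total) and a coverage for each of 203643 transcripts of 58382 genes. Of the transcripts 99.6% had the same identifier, ends and strand in GENCODE 29, which with a table of gene names gave symbols for 58262 genes and 19892 protein-coding genes. The files hold no read counts, so no count test was run. An FPKM of 0 can be a failed estimate, so such genes are given as listed at 0. A few genes on the sex chromosomes and 1 gene that the rule below named are not reported here.

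FPKM was summed over the transcripts of a gene. Library depth was estimated from coverage times transcript length, with 336 bases taken as 1 fragment, inferred from the lowest values of transcripts of at least 800 bases. The 99th percentile of coverage over FPKM gave the implied total of mapped bases. By this estimate fragments on nuclear protein-coding genes, in units of 1000, ranged from 103 to 2073 per library. A gene of low expression in the shallowest libraries therefore rests on few fragments.

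Values were divided by a scale factor, the median ratio of a library to the geometric mean over 1467 genes with FPKM of at least 1 in all 12 libraries (1310 protein-coding and 13 mitochondrial). The factors ranged from 0.192 to 3.19. This was not the planned scaling, which was log2(TPM + 1) with no further step. When the values proved to be FPKM, the values as deposited became the intended choice. The median ratio replaced them after the makeup of the libraries, the scale factors, the correlations of replicates and the median shifts between groups had been seen, and before any test was fitted. The reason was that mitochondrial transfer RNA made up 10.1 to 92.6% of the FPKM total of a library. Counts with TPM computed from that total and with FPKM as deposited stand beside each main count. They came from 7393 and 16957 genes tested, since the filter was applied anew to each scaling.

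Genes with a scaled FPKM of at least 1 in at least 2 libraries were tested (21367, of which 13171 protein-coding) on log2(scaled FPKM + 1). limma 3.58.1 (R 4.3.3) fitted 6 group means over all 12 libraries, with a trended prior, Benjamini-Hochberg adjustment and a threshold of 0.05 (6 residual and 2.02 prior degrees of freedom). The comparisons were each inhibitor against the controls in each line, their average, the inhibitors against each other in each line, the difference of each response between lines, and the control lines. Gene lists (32 lists, 720 of 723 genes matched) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The samples' groups, comparisons, lists, other settings except voom's scale, and rule for named genes were fixed before the data were examined. The rule took protein-coding genes with an adjusted p under 0.05, a mean scaled FPKM of at least 2 and every library of one group beyond every library of the other, and named the 10 largest rises and falls (5 between inhibitors, lines or controls). It added PRKD1, PRKD2 and PRKD3, up to 4 members of each called list with the smallest p, and 5 genes called in most of the 4 inhibitor comparisons. List members were named only for inhibitor comparisons and their average, a limit set after seeing how many there were, and for interactions the rule used deviations from the mean of the line's controls. The 12 genes of the expression plot were picked from the named genes after their values were seen.

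In simulated data, whose rates need not hold for groups of unequal spread, the fit was tested with genes changed by log2 1, 2 and 3. It recovered 1.49, 37.3 and 89.4% of them for kb-NB142-70 in OVCAR8, 0, 53.7 and 83.3% in SKOV3 and 35.8, 82.1 and 100% in the average, with 6 of 91, 5 of 96 and 3 of 148 calls false. Alternatives were other scalings (TPM, TPM over median ratios, FPKM as deposited, mitochondrial genes left out), a pseudocount of 0.1, no filter, a 2-fold threshold for shared calls, voom on estimated fragments, library weights, a replicate block, each line or only the named groups fitted alone, each library left out, fry, and an estimated correlation between genes. FPKM as deposited, TPM from the FPKM total, nuclear protein-coding genes alone and leaving out 5 libraries were added after the data were seen, and voom was rescaled to the 1467 genes after its first counts were seen. Those 5 had under 50% of the mapped bases on annotated transcripts or over 90% mitochondrial bases, limits set after the values were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.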

Results

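RNA sequencing of the human epithelial ovarian cancer lines OVCAR8 and SKOV3 looked for genes that respond to loss of protein kinase D (PKD) activity. PKD is a family of serine/threonine kinases encoded by PRKD1, PRKD2 and PRKD3. Each line was left without inhibitor or given 1 µM of CRT0066101 or of kb-NB142-70, small molecules that inhibit PKD, for 16 h, which made 6 groups of 2 libraries. The control titles name DMSO, the usual solvent, while their treatment label says untreated, so these groups are called controls. Labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between libraries, which may be technical. Pooling over the 6 groups understates it for OVCAR8 CRT0066101, whose libraries differed by 1.48 (root mean square log2), against 0.204 for OVCAR8 kb-NB142-70. Levels are FPKM divided by a scale factor per library, as mean ± SD (n = 2) or as each library's value where a library is listed at 0. Changes are differences of log2(scaled FPKM + 1), which understate the change of low genes, and are given as log2, for some genes also relative to the median gene, whose shift is given with each count where it moved. Medians of gene lists are relative to the median of all genes, which stands in parentheses after shares of higher calls where another scaling moved it, unless called fitted. Members of a list not said to rise or fall did not pass. Adjusted p values are from limma over 21367 genes. Coordinates are on hg38.

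The makeup of the libraries differed between groups and within the CRT0066101 groups. Mitochondrial transcripts took 41.6 and 37.1% of the bases on annotated transcripts in the OVCAR8 controls, 44.4 and 9.71% under CRT0066101 and 57.6 and 52.4% under kb-NB142-70. In SKOV3 they took 73.8 and 70.9% in the controls, 74.2 and 45.6% under CRT0066101 and 92.9 and 93.0% under kb-NB142-70. Nuclear protein-coding genes held 2.02 and 2.73% under kb-NB142-70 in SKOV3, against 19.3 and 22.6% in its controls. Nuclear ribosomal RNA took 5.82 and 17.1% in the SKOV3 CRT0066101 libraries and 0.573% in OVCAR8 CRT0066101 library 2, against 0.178 and 0.172% in the OVCAR8 controls and 0.0541 and 0.0490% in the SKOV3 controls. Annotated transcripts took 6.37% of the mapped bases in OVCAR8 CRT0066101 library 2, 34.8 and 23.5% in the SKOV3 CRT0066101 libraries and 64.1 to 89.0% in the other 9. Estimated fragments on nuclear protein-coding genes, in units of 1000, ranged from 103 and 111 in the SKOV3 kb-NB142-70 libraries to 2073 in OVCAR8 kb-NB142-70 library 2. Pearson's r between the libraries of a group, across genes, which are not independent, was 0.962 and 0.959 in the controls, 0.715 and 0.806 under CRT0066101, and 0.992 and 0.825 under kb-NB142-70, OVCAR8 first. No 2 libraries held the same values. Below, libraries are named by line, C for control, CRT or kb, and number. SKOV3 libraries of both inhibitors and OVCAR8 CRT2 are the 5 libraries of unusual makeup left out where stated.

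**Figure D1:**
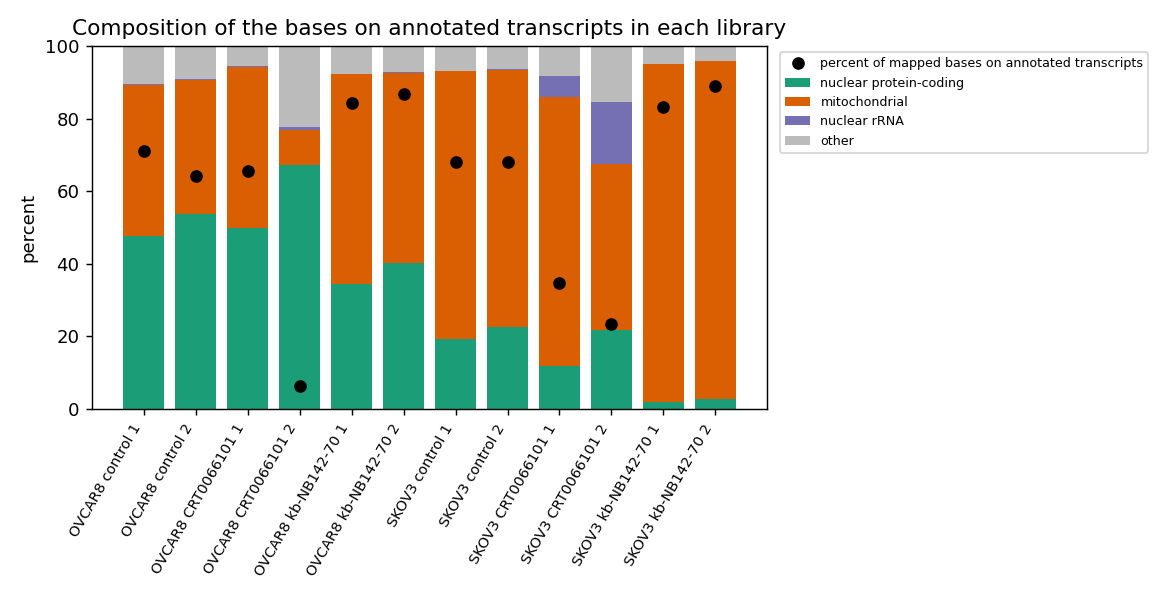
Percent of the bases on annotated transcripts (y axis) taken by mitochondrial, nuclear ribosomal, nuclear protein-coding and other transcripts in the 12 libraries (x axis), as stacked bars, with black points for the percent of mapped bases on annotated transcripts. Mitochondrial transcripts fill 92.9 and 93.0% of the SKOV3 kb-NB142-70 bars, and the black point of OVCAR8 CRT0066101 library 2 lies at 6.37%.

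The first comparison asked which genes respond to CRT0066101 in OVCAR8. CCN1, ANKRD1 and CCN2 of the YAP/TEAD program, a transcriptional output of the Hippo pathway, fell. CCN1 (gene ENSG00000142871, chromosome 1, 85580761 to 85583962), a secreted matricellular protein, fell from 134 ± 2.94 to 2.32 ± 1.71 (log2 -5.45, -5.87 relative, adjusted p = 5.14e-04). ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276) fell from 71.3 ± 0.0392 to 4.31 ± 2.58 (log2 -3.86, -4.28 relative, adjusted p = 0.00128). CCN2, a second matricellular protein, fell from 16.4 ± 0.634 to 0.384 ± 0.251 (log2 -3.67, -4.09 relative, adjusted p = 0.00791). CKS2 (ENSG00000123975, chromosome 9, 89311198 to 89316703), a subunit that binds cyclin-dependent kinases, fell from 91.0 ± 0.866 to 5.96 ± 1.15 (log2 -3.74, -4.16 relative, adjusted p = 5.14e-04). Falls also took in the histone H3.3 gene H3-3B (log2 -3.31), the beta-tubulin gene TUBB4B (log2 -3.44), the ribosome assembly gene NOP16 (log2 -3.53), TM2D2 (log2 -3.35) and SCAND1 (log2 -3.19). DNAJC14, a member of the HSP40 chaperone family, rose from 1.69 ± 0.0134 to 39.2 ± 2.55 (log2 3.90, 3.48 relative, adjusted p = 0.00727), and its locus overlaps ORMDL2. H4C16 and H2BC8, histone genes with near-identical copies, rose by log2 3.47 and log2 3.10. ACAP1, a GTPase-activating protein of Arf6, rose from 0.0587 ± 0.0343 to 10.3 ± 5.90 (log2 3.31, adjusted p = 0.00315), and DENND2B (log2 3.11), the focal adhesion kinase family member PTK2B (log2 2.40) and ARPP21 (values listed at 0 against 5.89 ± 0.594) rose too. HDLBP (log2 1.92), OPTN, an autophagy receptor (log2 1.82), and TXNDC12 (log2 1.76) rose as well. The median FPKM of olfactory receptor genes was 0.360 in OVCAR8 CRT2 (controls 0).

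Among 29 G2/M and mitosis genes, 5 fell, with CCNA2 (log2 -2.44), ANLN (log2 -1.35) and the kinase AURKA (log2 -2.17) beside CKS2 [10 fell adjusted over the list alone]. Camera adjusted p = 4.55e-13 (adjusted p = 0.106 with an estimated correlation) went with median -1.25. Of 26 G1/S and DNA replication genes, 2 fell, the replicative clamp PCNA (log2 -2.51) and the helicase subunit MCM4 (log2 -1.58) [6 fell adjusted over the list alone]. Camera adjusted p = 1.75e-08 (adjusted p = 0.106 with an estimated correlation) went with median -0.81. Among 19 YAP/TEAD target genes, 3 fell, which were CCN1, ANKRD1 and CCN2 [4 fell adjusted over the list alone]. Camera adjusted p = 1.11e-05 (adjusted p = 0.106 with an estimated correlation) went with median -0.76. Of 26 ERK output and immediate early genes, 2 fell, the AP-1 subunit FOSL1 (log2 -2.82) and the ERK phosphatase DUSP5 (log2 -1.54) [2 fell and 1 rose adjusted over the list alone]. Camera adjusted p = 0.0246 (adjusted p = 0.886 with an estimated correlation) went with median -0.60. Among 26 integrated stress response genes, 3 fell, the amino acid transporter chain SLC3A2 (log2 -3.04), STC2 (log2 -2.22) and SARS1 (log2 -1.23) [5 fell adjusted over the list alone]. Camera adjusted p = 3.67e-05 (adjusted p = 0.106 with an estimated correlation) went with median -0.66. Of 22 genes of the unfolded protein response of the ER, 1 fell, the ER chaperone HSPA5 (log2 -2.92) [2 fell adjusted over the list alone]. Camera adjusted p = 0.00359 (adjusted p = 0.106 with an estimated correlation) went with median -0.53.

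Among 20 heat shock response genes, 2 fell, the constitutive chaperone HSPA8 (log2 -3.15) and its partner DNAJA1 (log2 -2.28) [3 fell adjusted over the list alone]. Camera adjusted p = 1.86e-05 (adjusted p = 0.106 with an estimated correlation) went with median -0.98. Of 24 cholesterol biosynthesis and uptake genes, 1 fell, IDI1 of the isoprenoid pathway (log2 -1.40) [1 fell adjusted over the list alone]. Camera adjusted p = 0.00245 (adjusted p = 0.547 with an estimated correlation) went with median -0.70. Among 21 apoptosis regulators, 1 fell, the anti-apoptotic BCL2L1 (log2 -2.24) [3 fell adjusted over the list alone]. Camera adjusted p = 0.0460 (adjusted p = 0.876 with an estimated correlation) went with median -0.33 (fitted 0.10, mean -0.11, test downward). Of 13 mitochondrially encoded transcripts, none passed [0 adjusted over the list alone]. Camera adjusted p = 9.36e-04 (adjusted p = 0.792 with an estimated correlation) went with median -1.78. In all, 367 genes (76 higher, 291 lower) passed, and the median of all genes moved by 0.43. The higher share was 20.7%, against 15.4% of 13 (median 0.94) with TPM, 8.90% of 6282 (median -0.82) with FPKM as deposited, 58.6% of 1852 (median 0.67) with no mitochondrial genes, 40.3% of 2081 (median 0.73) with voom, 74.5% of 4356 (median 0.99) with voom as first scaled, 79.2% of 24 with library weights, 7.98% of 188 with nuclear protein-coding genes alone and 38.5% of 403 with a pseudocount of 0.1. The count was 124 and 125 without OVCAR8 C1 or C2, 9210 (88.7% higher) and 1547 without OVCAR8 CRT1 or CRT2, 198 without OVCAR8 kb1 or kb2, 627 without SKOV3 CRT1 or CRT2 and 7267 (35.5%) without the 5 libraries.

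kb-NB142-70 in OVCAR8 addressed the same question with the other inhibitor at the same dose and time. CKS2 fell from 91.0 ± 0.866 to 1.2 ± 0.203 (log2 -5.39, adjusted p = 6.89e-05), and CCNB1, the cyclin that drives entry into mitosis, fell from 26.7 ± 1.55 to 0.345 ± 0.0199 (log2 -4.36, adjusted p = 9.54e-04). H3-3B, which encodes histone H3.3, fell from 83.1 ± 2.35 to 1.82 ± 0.307 (log2 -4.90, adjusted p = 1.27e-04). The spliceosome and RNA decay genes SNRPD1 (log2 -3.89), SRSF3 (log2 -3.81), LSM6 (log2 -3.81) and EXOSC4 (log2 -3.71) fell, as did TIMM23, a protein import subunit of the mitochondrial inner membrane (log2 -3.84), TUBB4B (log2 -3.92) and NOL7 (log2 -3.87). CDKL1 rose from 0.353 ± 0.0537 to 26.9 ± 0.636 (log2 4.37, adjusted p = 0.00126), at a locus that overlaps DMAC2L. DNAJC14 rose from 1.69 ± 0.0134 to 35.0 ± 6.31 (log2 3.73, adjusted p = 0.00464), as did H4C16 (log2 3.83), the zinc finger gene ZNF616 (log2 3.64) and TALDO1, transaldolase of the pentose phosphate pathway (log2 2.28). HNRNPUL1 (log2 2.26), TXNDC12 (log2 2.33), CCDC57 (log2 3.64), PSKH1 (log2 2.55) and STRIT1, a regulator of the sarcoplasmic calcium pump (values listed at 0 against 8.32 ± 1.45), were higher too.

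Among 29 G2/M and mitosis genes, 14 fell, such as TPX2 (log2 -2.23) and ANLN (log2 -1.62) [21 fell adjusted over the list alone]. Camera adjusted p = 1.0e-18 (adjusted p = 0.199 with an estimated correlation) went with median -1.50. Of 26 G1/S and DNA replication genes, 7 fell, such as PCNA (log2 -3.69), MCM4 (log2 -2.78) and the licensing factor CDT1 (log2 -1.88) [11 fell adjusted over the list alone]. Camera adjusted p = 3.83e-05 (adjusted p = 0.299 with an estimated correlation) went with median -0.75. Among 19 YAP/TEAD target genes, 4 fell, ANKRD1 (log2 -2.64), CCN2 (log2 -2.78), AJUBA (log2 -2.25) and CCN1 (log2 -1.66) [6 fell adjusted over the list alone]. Camera adjusted p = 0.0316 (adjusted p = 0.325 with an estimated correlation) went with median -0.73. Of 26 integrated stress response genes, 6 fell, such as STC2 (log2 -3.54) and the transcription factor CEBPB (log2 -2.38) [9 fell adjusted over the list alone]. Camera adjusted p = 7.48e-04 (adjusted p = 0.199 with an estimated correlation) went with median -0.71. Among 20 heat shock response genes, 6 fell, such as HSPA8 (log2 -3.54) and the co-chaperone STIP1 (log2 -1.86) [11 fell and 2 rose adjusted over the list alone]. Camera adjusted p = 0.00108 (adjusted p = 0.199 with an estimated correlation) went with median -0.97. Of 24 cholesterol biosynthesis and uptake genes, 1 fell, IDI1 (log2 -1.72) [8 fell adjusted over the list alone]. Camera adjusted p = 7.48e-04 (adjusted p = 0.331 with an estimated correlation) went with median -1.02.

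Among 21 apoptosis regulators, 3 fell, the pro-apoptotic BAK1 (log2 -1.75) and the anti-apoptotic BCL2L1 (log2 -1.55) and MCL1 (log2 -1.23) [4 fell adjusted over the list alone]. Camera adjusted p = 0.0142 (adjusted p = 0.684 with an estimated correlation) went with median -0.45. Of 33 ribosomal protein genes, 5 rose, such as RPS27 (log2 1.57) and RPL14 (log2 1.16, but -0.16 with TPM) [13 rose adjusted over the list alone]. Camera adjusted p = 1.0e-18 (adjusted p = 0.199 with an estimated correlation) went with median 0.72. Among 29 nuclear-encoded respiratory chain genes, 8 rose, such as NDUFB8 of complex I (log2 2.01) and ATP5F1B of ATP synthase (log2 1.81) [1 fell and 12 rose adjusted over the list alone]. Camera adjusted p = 8.71e-10 (adjusted p = 0.199 with an estimated correlation) went with median 0.59. Of 11 drug efflux and detoxification genes, none passed [0 adjusted over the list alone]. Camera adjusted p = 0.0285 (adjusted p = 0.467 with an estimated correlation) went with median 0.26. Among 13 mitochondrially encoded transcripts, none passed [0 adjusted over the list alone]. Camera adjusted p = 0.00299 (adjusted p = 0.684 with an estimated correlation) went with median 1.33. In this comparison 1258 genes (268 higher, 990 lower) passed. Higher calls made up 21.3%, against 33.3% of 12 (median -0.83) with TPM, 13.9% of 6599 (median -0.50) with FPKM as deposited, 9.49% of 1275 (median -0.21) with TPM over median ratios, 10.4% of 3153 (median -0.25) with no mitochondrial genes, 53.2% of 3732 (median 0.85) with voom as first scaled, 32.6% of 11705 with library weights and 32.5% of 1956 with no filter. Counts were 319 (33.9% higher) and 299 without OVCAR8 C1 or C2, 3166 and 3189 without OVCAR8 CRT1 or CRT2, 311 and 306 (31.7%) without OVCAR8 kb1 or kb2, 801 and 798 without SKOV3 C1 or C2 and 8788 without the 5 libraries.

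In SKOV3, CRT0066101 was compared with its controls. ID1 (ENSG00000125968, chromosome 20, 31605283 to 31606515), an inhibitor of basic helix-loop-helix transcription factors, fell from 161 ± 2.56 to 4.71 ± 0.587 (log2 -4.83, -5.15 relative, adjusted p = 5.41e-05). CKS2 fell here too, from 64.2 ± 2.08 to 3.10 ± 0.872 (log2 -4.01, -4.33 relative, adjusted p = 7.91e-05). MTHFS, an enzyme of folate metabolism, went from 17.6 ± 6.38 to values listed at 0 (adjusted p = 9.45e-05) and CCDC12 from 17.1 ± 4.39 to values listed at 0 (adjusted p = 0.00398). MAZ, a zinc finger transcription factor, went from 17.9 ± 1.03 to 0.388 and 0 in the 2 libraries (log2 -4.00, -4.32 relative, adjusted p = 7.53e-04). The mitochondrial RNA polymerase gene POLRMT (log2 -3.69), CCDC85B (log2 -3.75), LRCH3 (log2 -3.73), ZNF28 (log2 -3.50) and IER5L (log2 -3.43) fell as well. RANBP2, a nucleoporin, rose from 0.300 ± 0.106 to 70.2 ± 21.8 (log2 5.74, 5.42 relative, adjusted p = 3.45e-04). ORC6, a subunit of the origin recognition complex, rose from 6.79 ± 0.725 to 142 ± 46.4 (log2 4.16, adjusted p = 0.0242), and ERBB3, a receptor of the epidermal growth factor receptor family, rose from 0.308 ± 0.155 to 20.5 ± 4.32 (log2 4.03, 3.71 relative, adjusted p = 5.02e-04). EXOC6 of the exocyst rose from values listed at 0 to 16.4 ± 2.54 (adjusted p = 2.04e-04), FLVCR2 from values listed at 0 to 11.3 ± 2.48 (adjusted p = 0.00960) and APLP1 from values listed at 0 to 10.7 ± 2.64 (adjusted p = 1.72e-04). PPM1N (log2 4.29), POGZ (log2 4.11), the forkhead gene FOXN3 (log2 3.92) and TBC1D3B, which has near-identical copies (log2 3.66), rose. In these libraries olfactory receptor genes had a median FPKM of 0.0974 and 0.196, against 0 in the controls, and 2 of 10 leukocyte and endothelial markers rose (camera adjusted p = 0.243).

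Of 20 NRF2 target genes, 6 fell, such as the thioredoxin reductase TXNRD1 (log2 -1.50), AKR1C1 (log2 -2.80) and AKR1C2 (log2 -1.75) [6 fell and 1 rose adjusted over the list alone]. Camera adjusted p = 0.00567 (adjusted p = 0.206 with an estimated correlation) went with median -0.84. Among 24 cholesterol biosynthesis and uptake genes, 2 fell, HMGCS1 (log2 -1.67) and PMVK (log2 -0.83) of the mevalonate pathway [1 fell adjusted over the list alone]. Camera adjusted p = 0.0279 (adjusted p = 0.774 with an estimated correlation) went with median -0.85. Of 19 YAP/TEAD target genes, 2 fell, CCN1 (log2 -1.73) and DLC1 (log2 -2.05) [2 fell adjusted over the list alone]. Camera adjusted p = 0.0259 (adjusted p = 0.50 with an estimated correlation) went with median -0.83. Among 20 heat shock response genes, 4 fell, such as DNAJA1 (log2 -2.56) and HSPA8 (log2 -2.03) [7 fell and 1 rose adjusted over the list alone]. Camera adjusted p = 0.0259 (adjusted p = 0.50 with an estimated correlation) went with median -0.69. Of 29 G2/M and mitosis genes, 6 fell and 1 rose, with AURKA (log2 -1.61) among the falls and ANLN as the rise (log2 0.96, but -0.36 with voom and -0.40 with FPKM as deposited) [6 fell and 1 rose adjusted over the list alone]. Camera adjusted p = 0.0126 (adjusted p = 0.774 with an estimated correlation) went with median -0.51. Among 26 G1/S and DNA replication genes, 4 fell, such as MCM4 (log2 -1.95) and PCNA (log2 -1.68) [4 fell adjusted over the list alone]. Camera adjusted p = 0.0318 (adjusted p = 0.774 with an estimated correlation) went with median -0.51. Of 33 ribosomal protein genes, 1 fell, RPL5 (log2 -1.22) [0 adjusted over the list alone]. Camera adjusted p = 0.0259 (adjusted p = 0.933 with an estimated correlation) went with median -0.53 (but 0.089 with TPM). In libraries with 5.82 and 17.1% nuclear ribosomal RNA, 3347 genes (2074 higher, 1273 lower) passed and the median of all genes moved by 0.32. The higher share was 62.0%, against 94.9% of 117 (median 0.076) with TPM, 21.2% of 6108 (median -0.57) with FPKM as deposited, 43.5% of 1356 (median 0.00) with TPM over median ratios, 5.84% of 6286 (median -0.63) with no mitochondrial genes, 79.6% of 2246 (median 1.13) with voom, 77.2% of 6412 (median 1.0) with voom as first scaled, 80.5% of 2908 with library weights and 45.6% of 1343 with nuclear protein-coding genes alone. Leaving out 1 library gave 7811 and 7825 without OVCAR8 CRT1 or CRT2, 2214 and 2216 without OVCAR8 kb1 or kb2 and 1512 and 1460 without SKOV3 C1 or C2.

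kb-NB142-70 was also compared in SKOV3. Of ERK output and immediate early genes, the latter transcribed within minutes of a stimulus, FOS rose from values listed at 0 to 30.9 ± 9.81 (adjusted p = 0.0143), EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) from 0.816 ± 0.521 to 31.0 ± 6.89 (log2 4.15, adjusted p = 8.03e-04) and FOSL1 from 5.64 ± 0.442 to 88.6 ± 24.1 (log2 3.73, adjusted p = 1.37e-04). SNAI2 (ENSG00000019549, chromosome 8, 48917604 to 48921740), a transcription factor of epithelial to mesenchymal transition, rose from 3.21 ± 1.25 to 75.5 ± 27.4 (log2 4.17, adjusted p = 5.55e-04). HSPA1A, the inducible HSP70, rose from 14.1 ± 0.489 to 236 ± 17.1 (log2 3.97, adjusted p = 0.00274) and has the near-identical copy HSPA1B, and ORC6 rose as well (log2 4.63). APOA1, the main apolipoprotein of high-density lipoprotein, went from 44.5 ± 16.6 to values listed at 0 (adjusted p = 0.00421). The globin genes HBB and HBA2, the second with a near-identical copy, fell from 119 ± 0.597 to 2.05 ± 0.656 (log2 -5.31, adjusted p = 9.28e-04) and from 144 ± 5.59 to 5.42 ± 2.12 (log2 -4.54, adjusted p = 5.55e-04). SHKBP1 (log2 -4.78), the innate immune transcription factor IRF3 (log2 -4.21) and AMTN (log2 -4.19) fell, and SSNA1 (19.6 ± 3.64 in the controls), MRPL14 of the mitochondrial ribosome (19.4 ± 2.45 in the controls), WDR18 (18.5 ± 1.02 in the controls) and MTHFS (17.6 ± 6.38 in the controls) were listed at 0 under kb-NB142-70.

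Among 26 ERK output and immediate early genes, 8 rose, such as JUN (log2 2.25) and ATF3 (log2 3.96) [9 rose adjusted over the list alone]. Camera adjusted p = 0.00486 (adjusted p = 0.736 with an estimated correlation) went with median 0.67 (but -0.071 with no mitochondrial genes). Of 27 mesenchymal and invasion markers, 8 rose, such as fibronectin FN1 (log2 1.90) and CD44 (log2 1.26), which were -0.65 and -1.29 with FPKM as deposited [2 fell and 8 rose adjusted over the list alone]. Camera adjusted p = 0.0324 (adjusted p = 0.547 with an estimated correlation) went with median 0.40 (but -0.28 with FPKM as deposited, -0.26 with no mitochondrial genes and -0.23 with voom). Among 13 mitochondrially encoded transcripts, 7 rose, such as MT-ND5 (log2 5.88) and MT-ND2 (log2 4.74), in libraries with 92.9 and 93.0% mitochondrial bases [9 rose adjusted over the list alone]. Camera adjusted p = 0.00106 (adjusted p = 0.675 with an estimated correlation) went with median 3.86. Of 29 nuclear-encoded respiratory chain genes, 13 fell and 2 rose, with ATP5F1A (log2 -2.36) and COX5B (log2 -2.21) among the falls [18 fell and 2 rose adjusted over the list alone]. Camera adjusted p = 3.57e-06 (adjusted p = 0.547 with an estimated correlation) went with median -1.08. Among 33 ribosomal protein genes, 16 fell, such as RPS3 (log2 -2.38) and RPS14 (log2 -2.88) [19 fell adjusted over the list alone]. Camera adjusted p = 1.51e-07 (adjusted p = 0.590 with an estimated correlation) went with median -0.87.

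Of 29 G2/M and mitosis genes, 8 fell, such as CKS2 (log2 -1.77) and CDK1, the mitotic kinase (log2 -2.02) [8 fell and 1 rose adjusted over the list alone]. Camera adjusted p = 0.00486 (adjusted p = 0.674 with an estimated correlation) went with median -0.54. Among 26 G1/S and DNA replication genes, 8 fell, such as thymidine kinase TK1 (log2 -2.38) and PCNA (log2 -2.82) [10 fell adjusted over the list alone]. Camera adjusted p = 0.0128 (adjusted p = 0.674 with an estimated correlation) went with median -0.11. Of 24 cholesterol biosynthesis and uptake genes, 5 fell, such as HMGCS1 (log2 -1.81) and PMVK (log2 -1.07) [6 fell adjusted over the list alone]. Camera adjusted p = 0.00486 (adjusted p = 0.590 with an estimated correlation) went with median -0.78. Among 20 NRF2 target genes, 4 fell, such as AKR1C1 (log2 -2.96) and transketolase TKT (log2 -1.17) [5 fell adjusted over the list alone]. Camera adjusted p = 0.0258 (adjusted p = 0.547 with an estimated correlation) went with median -0.65. Of 26 hypoxia and glycolysis genes, 5 fell and 1 rose, with the glucose transporter SLC2A1 (log2 -1.58) and enolase ENO1 (log2 -1.40) among the falls [7 fell and 1 rose adjusted over the list alone]. Camera adjusted p = 0.0275 (adjusted p = 0.547 with an estimated correlation) went with median -0.72. A total of 3710 genes (1757 higher, 1953 lower) passed. Higher calls made up 47.4%, against 75.0% of 4 (median -0.35) with TPM, 4.70% of 7677 (median -0.94) with FPKM as deposited, 33.0% of 2046 (median -0.12) with TPM over median ratios, 18.0% of 4732 (median -0.19) with no mitochondrial genes, 73.6% of 1616 (median 1.12) with voom, 78.1% of 7983 (median 0.91) with voom as first scaled and 35.1% of 2384 with nuclear protein-coding genes alone. Without 1 library the count was 7300 and 7326 without OVCAR8 CRT1 or CRT2, 1534 and 1491 without SKOV3 C1 or C2 and 2327 without SKOV3 kb1.

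The effect averaged over both inhibitors and both lines asked which genes move with PKD inhibition in general, and the genes for the PKD kinases themselves were read in every group. PRKD2 (ENSG00000105287, chromosome 19, 46674275 to 46717127) had 2.01 ± 0.0996 in the OVCAR8 controls, 0.937 ± 1.05 under CRT0066101 and 0.317 ± 0.0584 under kb-NB142-70, and 4.71 ± 0.162, 0.834 ± 0.479 and 0 and 0.278 in the 2 libraries in the SKOV3 groups. It fell in both SKOV3 comparisons (adjusted p = 0.0264 and adjusted p = 0.00606) and in the average (log2 change -1.49, adjusted p = 0.00623), and did not pass in OVCAR8 (adjusted p = 0.439 and adjusted p = 0.150). The difference of its response between the lines did not pass either (adjusted p = 0.499 for CRT0066101 and adjusted p = 0.285 for kb-NB142-70). PRKD1 (ENSG00000184304, chromosome 14, 29576479 to 30191898) and PRKD3 (ENSG00000115825, chromosome 2, 37250502 to 37324808) did not pass in the average (log2 change 0.63 and 0.77, adjusted p = 0.247 and adjusted p = 0.132), and their signs turned with voom and with FPKM as deposited, in that order. PRKD2 overlaps DACT3-AS1 and PRKD3 overlaps NDUFAF7, and the strand of the reads is not stated. CKS2 fell in the average (log2 change -3.73, -4.02 relative, adjusted p = 2.63e-05) and was lower in 8 of 8 treated libraries. ID1 (log2 -3.20, -3.49 relative), the glutaredoxin GLRX2 (log2 -3.01), the Wnt receptor FZD2 (log2 -2.93), the lactate transporter SLC16A3 (log2 -2.90), DCUN1D5 (log2 -2.79), SCAND1 (log2 -2.79), the linker histone H1-10 (log2 -2.79), MTHFS (log2 -2.89) and TUBB4B (log2 -2.78) fell too. DNAJC14 rose (log2 change 3.14, 2.85 relative, adjusted p = 8.80e-04), as did CCDC57 (log2 2.70), EGR1 (log2 2.17), RIMS2 (log2 2.07), ANKH (log2 1.94), IQCN (log2 1.64), MYLK3 (log2 1.63), the ketone body enzyme OXCT1 (log2 1.60), and MTRNR2L8 (log2 1.85) and MTRNR2L12 (log2 1.70), which are near-identical copies of mitochondrial ribosomal RNA.

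Among 29 G2/M and mitosis genes, 13 fell, such as CCNA2 (log2 -2.19) and AURKA (log2 -2.09) [17 fell adjusted over the list alone]. Camera adjusted p = 5.63e-11 (adjusted p = 0.283 with an estimated correlation) went with median -1.11. Of 26 G1/S and DNA replication genes, 11 fell, such as PCNA (log2 -2.67) and MCM4 (log2 -1.97) [12 fell adjusted over the list alone]. Camera adjusted p = 2.70e-06 (adjusted p = 0.283 with an estimated correlation) went with median -0.80. Among 24 cholesterol biosynthesis and uptake genes, 6 fell, such as TMEM97 (log2 -1.62) and IDI1 (log2 -1.05) [6 fell adjusted over the list alone]. Camera adjusted p = 5.47e-05 (adjusted p = 0.286 with an estimated correlation) went with median -0.79. Of 26 integrated stress response genes, 7 fell, such as CEBPB (log2 -2.05) and SLC3A2 (log2 -1.89) [8 fell and 2 rose adjusted over the list alone]. Camera adjusted p = 0.00106 (adjusted p = 0.283 with an estimated correlation) went with median -0.61. Among 20 heat shock response genes, 6 fell and 2 rose, with HSPA8 (log2 -2.42) and DNAJA1 (log2 -2.23) among the falls [7 fell and 2 rose adjusted over the list alone]. Camera adjusted p = 0.00398 (adjusted p = 0.283 with an estimated correlation) went with median -0.61. Of 21 apoptosis regulators, 5 fell and 1 rose, with MCL1 (log2 -1.58) and BAK1 (log2 -1.80) among the falls [5 fell and 1 rose adjusted over the list alone]. Camera adjusted p = 0.00943 (adjusted p = 0.794 with an estimated correlation) went with median -0.59.

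Among 19 YAP/TEAD target genes, 4 fell, such as CCN1 (log2 -1.73, but 0.10 with SKOV3 fitted alone) and ANKRD1 (log2 -1.82) [4 fell adjusted over the list alone]. Camera adjusted p = 0.0175 (adjusted p = 0.286 with an estimated correlation) went with median -0.52. Under kb-NB142-70 in SKOV3 2 YAP/TEAD target genes rose and 0 fell (median 0.64, but -0.56 with voom, camera adjusted p = 0.179), and 5 heat shock response genes rose and 4 fell (median 0.23, but below 0 under 5 other scalings, adjusted p = 0.953). Of 26 hypoxia and glycolysis genes, 4 fell, such as lactate dehydrogenase LDHA (log2 -2.24) and SLC2A1 (log2 -1.31) [4 fell adjusted over the list alone]. Camera adjusted p = 0.0414 (adjusted p = 0.380 with an estimated correlation) went with median -0.46. Averaged over groups, 3585 genes (1596 higher, 1989 lower) passed, and the median of all genes moved by 0.29. The higher share was 44.5%, against 70.8% of 65 (median -0.085) with TPM, 13.2% of 10626 (median -0.75) with FPKM as deposited, 29.2% of 2170 (median -0.086) with TPM over median ratios, 15.2% of 6712 (median -0.19) with no mitochondrial genes, 59.3% of 6710 (median 0.59) with voom, 77.4% of 11130 (median 0.81) with voom as first scaled, 68.8% of 5974 with library weights, 21.2% of 1938 with nuclear protein-coding genes alone, 32.2% of 2044 with the replicate block, 16.1% of 551 with OVCAR8 fitted alone and 62.0% of 4914 with SKOV3 fitted alone. Omitting 1 library gave 1275 (32.5% higher) and 1156 (30.4%) without OVCAR8 C1 or C2, 10281 (70.4%) and 7729 without OVCAR8 CRT1 or CRT2, 2176 and 2198 without OVCAR8 kb1 or kb2 and 1866 and 1879 without SKOV3 C1 or C2.

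**Figure D2:**
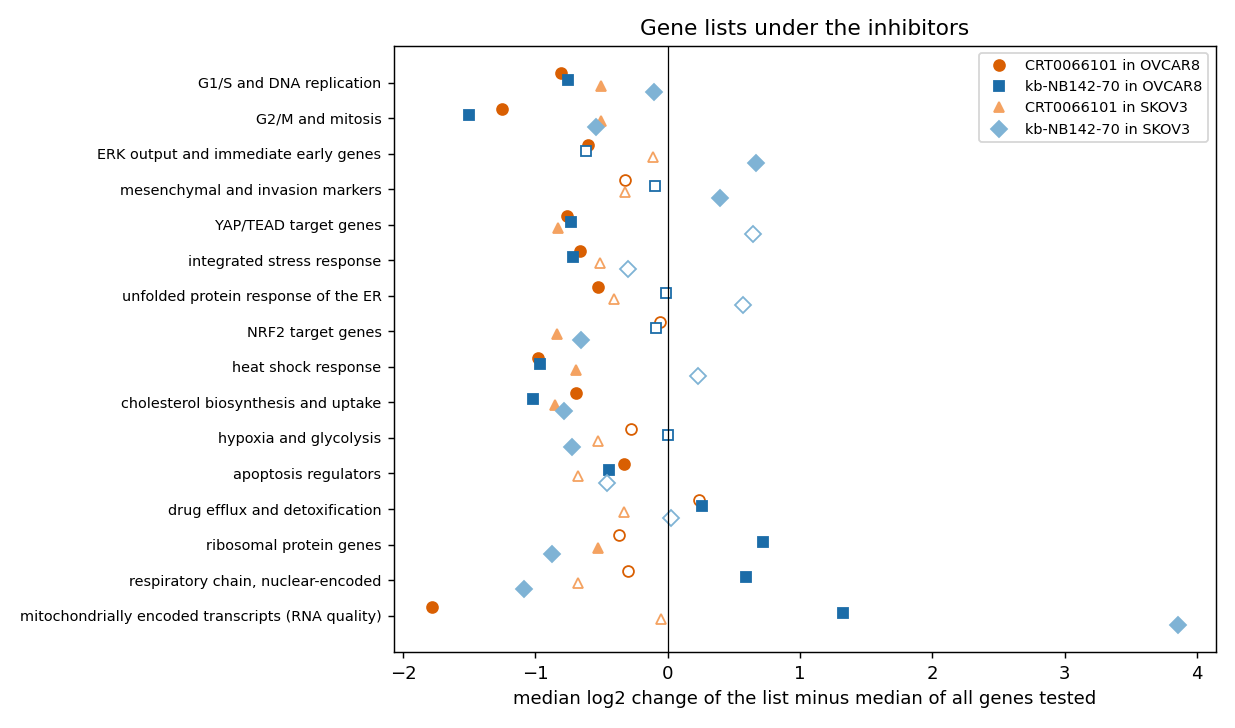
Median log2 change of each gene list minus the median of all genes tested (x axis) for the lists on the y axis, with circles and squares for CRT0066101 and kb-NB142-70 in OVCAR8, triangles and diamonds for the same in SKOV3, and filled symbols where camera gave an adjusted p under 0.05. G2/M and mitosis lies at -1.25, -1.50, -0.51 and -0.54 in that order.

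The inhibitors were then compared with each other in OVCAR8 at 1 µM and 16 h, where higher means higher under CRT0066101. KLF6 (ENSG00000067082, chromosome 10, 3775996 to 3785281), a zinc finger transcription factor, was lower, from 81.7 ± 9.44 to 2.31 ± 2.34 (log2 -4.84, adjusted p = 0.00234), reading kb-NB142-70 first. CCN1 was lower, from 41.8 ± 0.613 to 2.32 ± 1.71 (log2 -3.79, adjusted p = 0.00243), as were CDKL1 (log2 -3.44), STRIT1 (log2 -2.84) and PSKH1 (log2 -1.97, but 0.27 with TPM). Higher under CRT0066101 were ACAP1 (log2 3.32), DENND2B (log2 3.14), AATF (log2 2.95), LSM6 (log2 2.89) and ARPP21 (log2 2.73), with adjusted p = 0.00176 to adjusted p = 0.0453. Called genes [adjusted over the list alone] were 3 higher [7 higher] of 29 G2/M and mitosis genes (median 0.35, but -0.28 with voom), 1 lower [1 lower] of 19 YAP/TEAD target genes (median -0.98) and 0 [13 lower] of 33 ribosomal protein genes (median -1.34). Camera adjusted p = 1.60e-04, 8.42e-04 and 5.67e-39 became adjusted p = 0.381, 0.152 and 0.103 with an estimated correlation. Members called [adjusted over the list alone] were 1 lower [7 lower] of 29 nuclear-encoded respiratory chain genes (median -1.16), 0 [0] of 13 mitochondrially encoded transcripts (median -3.07) and 0 [0] of 26 hypoxia and glycolysis genes (median -0.11, fitted 0.48, mean 0.27, test downward, but 0.016 with TPM). Camera adjusted p = 8.11e-20, 1.19e-14 and 0.0368 became adjusted p = 0.103, 0.172 and 0.316 with an estimated correlation. Mitochondrial shares differed, as given above.

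Genes called [adjusted over the list alone] were 0 [1 lower and 1 higher] of 27 mesenchymal and invasion markers (median -0.33, fitted 0.25, mean 0.19, test downward), 0 [0] of 22 genes of the unfolded protein response of the ER (median -0.41, fitted 0.17, mean 0.04, test downward), 0 [0] of 20 NRF2 target genes (median -0.31, fitted 0.28, mean 0.15, test downward) and 1 lower [1 lower] of 18 replication-dependent histone transcripts (median -0.54, fitted 0.04, mean 0.07, test downward). Camera adjusted p = 0.0368, 0.0126, 0.0368 and 0.00914 became adjusted p = 0.187, 0.152, 0.172 and 0.172 with an estimated correlation. Between the inhibitors 202 genes (99 higher, 103 lower) passed, the median of all genes stood 0.59 higher under CRT0066101, and the median standard error of a gene was 0.46, so genes that did not pass are not shown to respond alike. Higher calls made up 49.0%, against 12.5% of 8 (median 1.81) with TPM, 35.9% of 1241 (median 0.00) with FPKM as deposited, 81.0% of 137 (median 0.34) with TPM over median ratios, 89.9% of 3079 (median 1.21) with no mitochondrial genes, 82.9% of 1085 (median 1.42) with voom, 74.1% of 1409 (median 0.46) with voom as first scaled, 94.4% of 18 with library weights, 70.3% of 37 with nuclear protein-coding genes alone, 67.8% of 481 with a pseudocount of 0.1, 36.4% of 763 with no filter, 27.0% of 100 with the replicate block and 15.4% of 13 with the line fitted alone. With 1 library omitted the count was 138 (31.9% higher) and 135 (32.6%) without OVCAR8 C1 or C2, 11197 (92.0%) and 368 without OVCAR8 CRT1 or CRT2, 99 (22.2%) and 102 (21.6%) without OVCAR8 kb1 or kb2, 429 and 435 without SKOV3 CRT1 or CRT2 and 4437 (60.6%) without the 5 libraries.

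In SKOV3 the inhibitors were compared in the same way. SNAI2 went from 75.5 ± 27.4 to 0.336 ± 0.0970 (log2 -5.79, -6.07 relative, adjusted p = 7.52e-05) from kb-NB142-70 to CRT0066101. The splicing-related ARGLU1 (log2 -4.59) and RSRC2 (log2 -4.24), the lipase inhibitor G0S2 (log2 -4.31) and the mitochondrial MT-CO1 (log2 -4.24) were lower as well. HBB went from 2.05 ± 0.656 to 195 ± 172 (log2 5.67, 5.40 relative, adjusted p = 3.89e-04), APOA1 from values listed at 0 to 44.8 ± 12.2 (adjusted p = 0.00314) and RANBP2 from 1.13 ± 0.557 to 70.2 ± 21.8 (log2 5.05, adjusted p = 5.35e-04), the last at -0.17 with voom. HBA2 (log2 4.98) and HBA1 (log2 4.39), which are near-identical copies, were higher. PRKD1 was listed at 0 in both kb-NB142-70 libraries and had 3.34 ± 0.124 under CRT0066101 (adjusted p = 0.0394). Called [adjusted over the list alone] were 5 lower [6 lower] of 19 YAP/TEAD target genes (median -1.21), 8 lower and 2 higher [11 lower and 2 higher] of 26 ERK output and immediate early genes (median -1.19) and 6 lower and 1 higher [6 lower and 1 higher] of 27 mesenchymal and invasion markers (median -0.73, but 0.27 with TPM). Camera adjusted p = 2.79e-04, 0.00305 and 0.00842 became adjusted p = 0.258, 1.0 and 0.258 with an estimated correlation. Called genes [adjusted over the list alone] were 5 lower and 3 higher [10 lower and 3 higher] of 20 heat shock response genes (median -1.18, but 0.29 with TPM), 12 higher [14 higher] of 33 ribosomal protein genes (median 0.43, but -0.59 with no mitochondrial genes) and 1 lower and 11 higher [1 lower and 12 higher] of 29 nuclear-encoded respiratory chain genes (median 0.52, but -0.36 with no mitochondrial genes). Camera adjusted p = 0.00856, 0.00779 and 0.0257 became adjusted p = 0.258, 1.0 and 1.0 with an estimated correlation.

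Members called [adjusted over the list alone] were 8 lower [11 lower] of 13 mitochondrially encoded transcripts (median -4.08). Camera adjusted p = 1.27e-04 became adjusted p = 1.0 with an estimated correlation. Mitochondrial shares differed, as given above. In SKOV3 4143 genes (2649 higher, 1494 lower) differed, and the median of all genes stood 0.27 higher under CRT0066101. The higher share was 63.9%, against 98.5% of 204 (median 0.55) with TPM, 85.5% of 1812 with FPKM as deposited, 18.4% of 1883 (median -0.30) with no mitochondrial genes, 51.5% of 231 (median 0.068) with voom and 50.9% of 1800 (median 0.15) with voom as first scaled. The count reached 7948 and 7970 without OVCAR8 CRT1 or CRT2.

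Interaction tests asked whether the lines respond differently to CRT0066101, with positive values for a response more upward in SKOV3. ERBB3 differed (log2 difference 5.42, adjusted p = 0.00174), going from 19.1 ± 1.81 to 7.54 ± 5.42 in OVCAR8 and from 0.308 ± 0.155 to 20.5 ± 4.32 in SKOV3. RANBP2 (5.30), AC009086.2 (4.88), the nucleoporin NUP85 (4.56) and the cap-binding EIF4E2 (4.08) followed on that side. ZNF28 (-5.04), LRCH3 (-4.40, but 0.58 with voom), SAMD11 (-4.20), TSTD1 (-4.01) and the histone gene HIST1H3C (-3.99) lay on the other. Genes called [adjusted over the list alone] were 2 lower [2 lower] of 20 NRF2 target genes (median -1.02). Camera adjusted p = 0.00563 became adjusted p = 0.205 with an estimated correlation. Mitochondrial shares are given above. The interaction passed for 1433 genes (945 higher, 488 lower), 414 of them protein-coding (201 higher, 213 lower). Higher calls made up 66.0%, against 100% of 50 (median -0.80) with TPM, 63.9% of 4097 (median 0.24) with FPKM as deposited, 12% of 5272 (median -1.44) with no mitochondrial genes, 80.4% of 194 (median 0.30) with voom, 50.6% of 1625 with voom as first scaled, 88.5% of 594 with library weights and 79.7% of 865 with the named groups alone. Omitting libraries singly gave 811 (76.0% higher) and 805 (77.9%) without OVCAR8 C1 or C2 and 5654 (26.4%) and 4784 without OVCAR8 CRT1 or CRT2.

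The same test was made for kb-NB142-70. HSPA1A (log2 difference 6.62, adjusted p = 0.00244) went from 9.57 ± 0.242 to 0.691 ± 0.0490 in OVCAR8 and from 14.1 ± 0.489 to 236 ± 17.1 in SKOV3. FOSL1 (4.96, adjusted p = 8.10e-04) went from 24.4 ± 0.484 to 9.83 ± 0.423 and from 5.64 ± 0.442 to 88.6 ± 24.1, and HSPA5 (4.91, adjusted p = 0.00189) from 46.0 ± 0.234 to 5.88 ± 0.151 and from 24.6 ± 2.28 to 117 ± 50.7. HSPA1B (5.95) and UTP23 (4.91) were on the same side, while APOA1 (-5.57), ZNF28 (-5.46), MTCP1 (-5.36), CDKL1 (-4.91) and HIST1H3C (-4.70) lay on the opposite one. Called [adjusted over the list alone] were 3 lower and 7 higher [3 lower and 10 higher] of 20 heat shock response genes (median 1.14, but -0.17 with voom), 6 higher [12 higher] of 26 ERK output and immediate early genes (median 1.13), 4 higher [5 higher] of 19 YAP/TEAD target genes (median 1.30) and 4 higher [6 higher] of 29 G2/M and mitosis genes (median 0.81). Camera adjusted p = 0.0336, 3.83e-04, 0.0149 and 0.00105 became adjusted p = 0.303, 0.660, 0.303 and 0.597 with an estimated correlation.

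Called genes [adjusted over the list alone] were 3 lower [4 lower] of 20 NRF2 target genes (median -0.91), 21 lower [26 lower] of 33 ribosomal protein genes (median -1.83) and 14 lower and 1 higher [20 lower and 1 higher] of 29 nuclear-encoded respiratory chain genes (median -2.32). Camera adjusted p = 0.00199, 4.71e-21 and 4.88e-14 became adjusted p = 0.187, 0.258 and 0.187 with an estimated correlation. Mitochondrial shares are given above, and mitochondrially encoded transcripts had a median of 2.02 (camera adjusted p = 0.147). In the interaction 1970 genes (1149 higher, 821 lower) passed, with the median of all genes at 0.23. The higher share was 58.3%, against 60% of 5 (median 0.42) with TPM, 44.1% of 4199 (median -0.33) with FPKM as deposited, 46.8% of 2140 with no mitochondrial genes and 80.8% of 1702 (median 1.87) with voom. Single omissions gave 824 and 796 without OVCAR8 C1 or C2, 5525 and 5555 without OVCAR8 CRT1 or CRT2, 825 and 798 without OVCAR8 kb1 or kb2 and 1095 and 1098 without SKOV3 C1 or C2.

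The controls gave the baseline of the lines, with higher meaning higher in SKOV3. S100A4, a calcium-binding protein tied to cell motility, had 2.84 ± 0.0532 in OVCAR8 and 416 ± 7.18 in SKOV3 (log2 difference 6.76, adjusted p = 8.32e-06). UBB and the protease inhibitor SLPI were listed at 0 in both OVCAR8 controls and had 115 ± 6.79 and 28.8 ± 1.46 in SKOV3, and the cancer-testis genes SPANXB1 and SPANXC, which are close copies, had 285 ± 4.33 and 39.1 ± 4.6. The metallothionein MT1E (log2 difference -7.00), UQCRH of respiratory complex III (-6.25) and ANKRD1 (-5.36) were lower in SKOV3, and CRIP1 and LY6K had 87.5 ± 1.58 and 61.2 ± 4.22 in OVCAR8 and were listed at 0 in SKOV3. Members called [adjusted over the list alone] were 7 higher [13 higher] of 20 NRF2 target genes (median 1.0), 1 lower and 4 higher [1 lower and 6 higher] of 21 NF-kB target genes (median 0.85) and 1 lower and 4 higher [3 lower and 7 higher] of 26 hypoxia and glycolysis genes (median 0.82, but -0.11 with voom). Camera adjusted p = 6.71e-08, 0.0162 and 0.0187 became adjusted p = 0.0217, 0.807 and 0.438 with an estimated correlation. Genes called [adjusted over the list alone] were 4 lower [5 lower and 2 higher] of 19 YAP/TEAD target genes (median -0.47) and 6 lower [9 lower] of 26 integrated stress response genes (median -0.52). Camera adjusted p = 0.00185 and 4.61e-04 became adjusted p = 0.177 and 0.177 with an estimated correlation.

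Called [adjusted over the list alone] were 2 lower [8 lower] of 22 genes of the unfolded protein response of the ER (median -0.30), 6 lower [11 lower and 1 higher] of 33 ribosomal protein genes (median -0.49) and 5 lower [6 lower and 2 higher] of 29 nuclear-encoded respiratory chain genes (median -0.22). Camera adjusted p = 0.00642, 7.15e-09 and 0.0255 became adjusted p = 0.177, 0.534 and 0.807 with an estimated correlation. Called genes [adjusted over the list alone] were 2 lower [2 lower] of 29 G2/M and mitosis genes (median -0.29) and 0 [0] of 13 mitochondrially encoded transcripts (median 1.80). Camera adjusted p = 0.0229 and 0.0205 became adjusted p = 0.807 and 0.860 with an estimated correlation. Mitochondrial shares differed, as given above. Between the controls 1424 genes (777 higher, 647 lower) passed. Higher calls made up 54.6%, against 9.38% of 96 (median -0.93) with TPM, 28% of 6510 (median -0.56) with FPKM as deposited and 36.3% of 2636 with no mitochondrial genes. The count of line differences was 444 and 475 without OVCAR8 C1 or C2, 3844 and 3865 without OVCAR8 CRT1 or CRT2, 893 and 898 without OVCAR8 kb1 or kb2, 626 and 629 without SKOV3 C1 or C2 and 10202 without the 5 libraries.

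The calls of different comparisons overlapped mostly among falls. Lower in all 4 inhibitor comparisons were 63 genes, and 1 was higher in all 4. FZD2 went from 8.71 ± 0.478 to 0.619 ± 0.104 under CRT0066101 and 0.0339 ± 0.00555 under kb-NB142-70 in OVCAR8, and from 7.93 ± 0.608 to 0 and 0.765 in the 2 libraries under CRT0066101 in SKOV3, where kb-NB142-70 libraries were listed at 0. The histone H2AX, a mark of DNA damage when phosphorylated, had 10.4 ± 0.326, 1.34 ± 1.21 and 0.137 ± 0.0166 in the OVCAR8 groups and 20.5 ± 0.0998, 2.26 ± 0.844 and 2.58 ± 0.897 in the SKOV3 groups. GLRX2, SCAND1 and the centromere gene CENPB were also lower in all 4, CENPB by log2 -2.25, -2.99, -2.42 and -2.38. In OVCAR8 the inhibitors shared 265 falls (13.5 for independent lists) and 15 rises (0.953), with 2 genes in opposite directions. In SKOV3 they shared 833 falls (116) and 268 rises (170.5), with 48 opposite. Unchanged groups simulated against the same controls shared 0 calls in 100 draws, no yardstick since unchanged genes rarely pass. Pearson's r of the changes was 0.572 in OVCAR8 and 0.474 in SKOV3 (simulated 0.502 and 0.50), and covariance 0.377 and 0.725 (0.163 and 0.162). Controls of 2 libraries cannot be split into 2 pairs, so sharing them may explain part of the overlap.

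Between the lines, which share no controls, CRT0066101 gave 99 shared falls (17.3 for independent lists), 13 shared rises (7.38) and 10 opposite genes. kb-NB142-70 gave 348 shared falls (90.5), 22 shared rises (22) and 71 opposite genes.

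**Figure D3:**
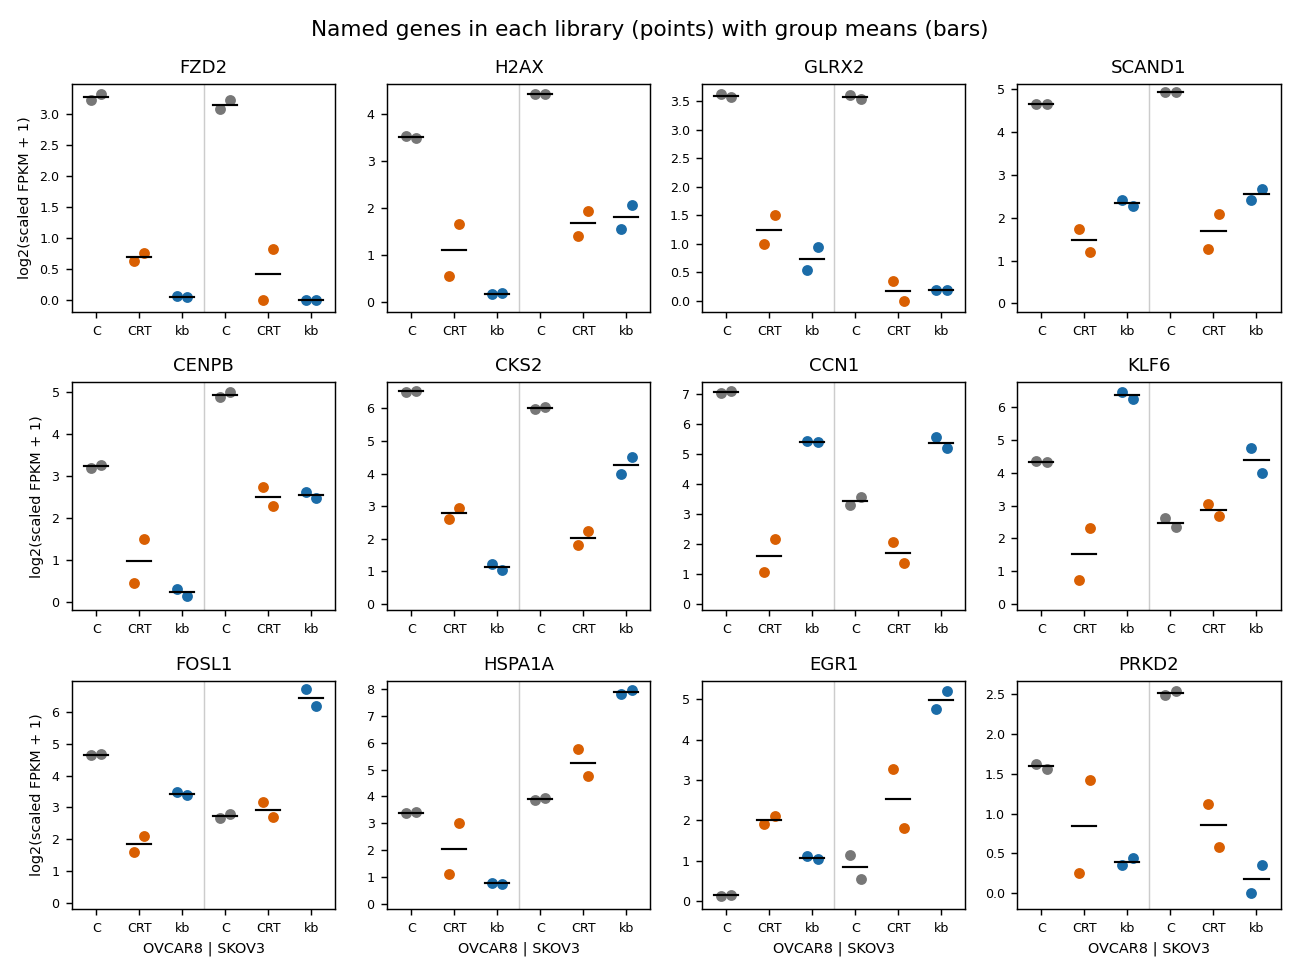
Expression of 12 named genes as log2(scaled FPKM + 1) (y axis) in the control (C), CRT0066101 (CRT) and kb-NB142-70 (kb) groups of OVCAR8 and SKOV3 (x axis), with points for libraries and bars for group means. FOSL1 falls to 9.83 ± 0.423 in OVCAR8 and rises to 88.6 ± 24.1 in SKOV3 under kb-NB142-70, as scaled FPKM.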

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

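The tests on olfactory receptor genes and on gene length and GC content, the bootstrap interval and correlations for a wrong label, and the limits behind the ribosomal RNA and olfactory receptor values, were chosen after the results were seen. OVCAR8 CRT0066101 library 2 stood apart from the other OVCAR8 libraries, with 6.37% of its mapped bases on annotated transcripts. Few fragments alone were argued against, since over genes in the top quartile of mean expression its Spearman correlation with the other OVCAR8 libraries averaged 0.557, against 0.760 for the next lowest library. A candidate explanation is genomic DNA or other reads that do not depend on transcription. The median FPKM, as deposited, of 381 olfactory receptor genes was 0.360 in library 2 and 0 in the other OVCAR8 libraries. A SKOV3 library under a wrong label was argued against: its median position between the OVCAR8 controls (0) and the SKOV3 controls (1) was 0.241 (bootstrap interval 0.202 to 0.268), where over 0.5 was needed and SKOV3 inhibitor libraries lay at 0.609 to 0.635, and its Pearson's r across genes was 0.672 to 0.715 with OVCAR8 and 0.522 to 0.620 with SKOV3 libraries. The position met the bound of 0.25 first set for exclusion, although the interval, required later, passed it, and neither a mixed sample nor an effect of CRT0066101 was tested.

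The large number of genes called for kb-NB142-70 in SKOV3 came from libraries with few nuclear fragments. As a test of low depth, 26.8% of genes in the top quartile of mean expression were called against 14.2% of the rest. Changes of low genes are understated on this scale, so a higher rate in the top quartile does not decide whether low depth was the cause. Gene length and GC content accounted for 3.46% of the variance of the log2 changes. The mitochondrial share and the treatment go together in these libraries, so a response to the inhibitor and a difference of RNA content cannot be separated by design, and a biological response remained untested.

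In OVCAR8 some genes with short-lived transcripts, such as CCN1 and CCN2, fell under both inhibitors. A general loss of such transcripts was tested on 341 zinc finger genes, whose transcripts tend to be short-lived. They lay 0.0550 and 0.0375 (log2) above matched genes under CRT0066101 and kb-NB142-70. Falls are understated where such genes are low, so the test cannot decide. Whether the falls of single genes reflect PKD was not tested.

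The response to CRT0066101 differed between the lines, by the interaction test, for 1433 genes. As the log2 response in SKOV3 minus that in OVCAR8, it was above 0 for AC009086.2 (4.88), ANKRD1 (3.21), APLP1 (2.75), CCN1 (3.72), CCN2 (3.43), EIF4E2 (4.08), ERBB3 (5.42), EXOC6 (3.91), FOXN3 (3.09), H3-3B (1.94), NUP85 (4.56), PPM1N (3.59), RANBP2 (5.30) and TM2D2 (3.49). It was below 0 for DENND2B (-3.97), H4C16 (-3.12), HDLBP (-3.26), HIST1H3C (-3.99), ID1 (-2.43), IER5L (-2.97), LRCH3 (-4.40), MTHFS (-2.61), OPTN (-2.11), SAMD11 (-4.20), TSTD1 (-4.01), TXNDC12 (-2.16) and ZNF28 (-5.04). Among lists, NRF2 target genes (-1.02) differed (adjusted p = 0.205 with an estimated correlation). The response to kb-NB142-70 differed in the same test for 1970 genes, above 0 for CCNB1 (3.61), CKS2 (3.61), EGR1 (3.21), FOSL1 (4.96), H3-3B (4.21), HSPA1A (6.62), HSPA1B (5.95), HSPA5 (4.91), LSM6 (2.86), SNAI2 (4.28) and UTP23 (4.91). On the other side were AMTN (-4.19), APOA1 (-5.57), CDKL1 (-4.91), H4C16 (-3.83), HBA2 (-3.42), HBB (-3.72), HIST1H3C (-4.70), HNRNPUL1 (-1.78), MRPL14 (-2.50), MTCP1 (-5.36), MTHFS (-2.52), PSKH1 (-3.69), SHKBP1 (-4.40), SSNA1 (-2.63), STRIT1 (-3.21), TALDO1 (-2.46), TXNDC12 (-1.93), ZNF28 (-5.46) and ZNF616 (-3.25). The lists that differed, by fitted median, were G2/M and mitosis (1.03), ERK output and immediate early genes (1.36), YAP/TEAD target genes (1.52), NRF2 target genes (-0.68), heat shock response (1.36), ribosomal protein genes (-1.61) and respiratory chain (-2.09). None held with an estimated correlation (adjusted p = 0.187 to 0.660), and heat shock response was -0.26 with FPKM as deposited, where the median gene was -0.33.

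Data outside the comparisons also stood above the controls. The median FPKM of olfactory receptor genes was 0.36 in OVCAR8 CRT2, 0.0974 in SKOV3 CRT1 and 0.196 in SKOV3 CRT2 (controls 0). Nuclear ribosomal RNA took 0.573, 5.82 and 17.1% of these libraries, in that order.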

How the results depend on the processing

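FPKM as deposited, TPM from the FPKM total, nuclear protein-coding genes alone and the omission of 5 libraries were chosen after the data were seen. So were voom's rescaling and the median ratio, which replaced TPM and then FPKM as deposited. Counts over 1.5 times from those reported follow. Spread is pooled over the groups of a fit, so dropping groups of wide spread can raise counts. Other causes were not tested. FPKM as deposited gave 6282 (OVCAR8 CRT), 6599 (OVCAR8 kb), 6108 (SKOV3 CRT), 7677 (SKOV3 kb), 10626 (average), 1241 (OVCAR8 inhibitors), 1812 (SKOV3 inhibitors), 4097 (CRT between lines), 4199 (kb between lines) and 6510 (control lines). TPM gave 13 (OVCAR8 CRT), 12 (OVCAR8 kb), 117 (SKOV3 CRT), 4 (SKOV3 kb), 65 (average), 8 (OVCAR8 inhibitors), 204 (SKOV3 inhibitors), 50 (CRT between lines), 5 (kb between lines) and 96 (control lines). TPM over median ratios gave 1356 (SKOV3 CRT), 2046 (SKOV3 kb), 2170 (average), 1707 (SKOV3 inhibitors), 677 (CRT between lines) and 1275 (kb between lines). With mitochondrial genes left out the counts were 1852 (OVCAR8 CRT), 3153 (OVCAR8 kb), 6286 (SKOV3 CRT), 6712 (average), 3079 (OVCAR8 inhibitors), 1883 (SKOV3 inhibitors), 5272 (CRT between lines) and 2636 (control lines). voom gave 2081 (OVCAR8 CRT), 4309 (OVCAR8 kb), 1616 (SKOV3 kb), 6710 (average), 1085 (OVCAR8 inhibitors), 231 (SKOV3 inhibitors), 194 (CRT between lines) and 3018 (control lines), and as first scaled, over genes with at least 1 estimated fragment in all libraries, 4356 (OVCAR8 CRT), 3732 (OVCAR8 kb), 6412 (SKOV3 CRT), 7983 (SKOV3 kb), 11130 (average), 1409 (OVCAR8 inhibitors), 1800 (SKOV3 inhibitors) and 3783 (control lines). Library weights gave 24 (OVCAR8 CRT), 11705 (OVCAR8 kb), 5974 (average), 18 (OVCAR8 inhibitors), 2712 (SKOV3 inhibitors), 594 (CRT between lines), 6531 (kb between lines) and 9860 (control lines). Nuclear protein-coding genes alone gave 188 (OVCAR8 CRT), 1343 (SKOV3 CRT), 2384 (SKOV3 kb), 1938 (average), 37 (OVCAR8 inhibitors), 1873 (SKOV3 inhibitors), 67 (CRT between lines) and 1030 (kb between lines). No filter gave 908 (OVCAR8 CRT), 1956 (OVCAR8 kb) and 763 (OVCAR8 inhibitors). A pseudocount of 0.1 gave 481 (OVCAR8 inhibitors). A fit of the line alone gave 191 (OVCAR8 CRT), 777 (OVCAR8 kb) and 13 (OVCAR8 inhibitors), one of the named groups 865 (CRT between lines), 8766 (kb between lines) and 7988 (control lines), and one of OVCAR8 551 (average). Without the 5 libraries the counts were 7267 (OVCAR8 CRT), 8788 (OVCAR8 kb), 4437 (OVCAR8 inhibitors) and 10202 (control lines), and the other 6 comparisons lost a group and gave no value.

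Omitting 1 library gave between 124 and 9210 (OVCAR8 CRT), 299 and 3189 (OVCAR8 kb), 1460 and 7825 (SKOV3 CRT), 1491 and 7326 (SKOV3 kb), 1156 and 10281 (average), 99 and 11197 (OVCAR8 inhibitors), 2860 and 7970 (SKOV3 inhibitors), 805 and 5654 (CRT between lines), 796 and 5555 (kb between lines) and 444 and 3865 (control lines), with the lone library of a group assumed to vary like the others. Calls shared by the inhibitors were 4747 in OVCAR8 and 4580 in SKOV3 with FPKM as deposited, and 699 in SKOV3 with TPM over median ratios. Those shared by the lines were 2697 under CRT0066101 and 3277 under kb-NB142-70 with FPKM as deposited. Of 81 list calls, 1, NRF2 target genes between the control lines, held with an estimated correlation, 67 with a pseudocount of 0.1, 51 with fry and 30 with FPKM as deposited, while TPM over median ratios called 40 lists, 37 of them among the 81, and TPM 38, 31 of them.

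In the labels only the second library of a group carries a number, and deviations from the group means correlated at -0.165 to 0.0740 between groups of a line, so the libraries were not treated as paired. The replicate block gave 166 (OVCAR8 CRT), 596 (OVCAR8 kb), 2044 (average), 100 (OVCAR8 inhibitors), 887 (CRT between lines), 1138 (kb between lines) and 504 (control lines), with 319 of 369 named values and 78 of 81 list calls kept on their side of the threshold.

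With TPM, fitted log2 changes, not relative to the median gene, turned sign for OVCAR8 CRT (PRKD2 0.37, MANF 0.74, STIP1 0.55, SERPINH1 0.078, TMEM97 0.12, EBP 0.37, MVD 0.22), OVCAR8 kb (GSTK1 -0.19, GSTP1 -0.51, GSTM3 -0.50, RPL14 -0.16, RPL37 -0.15), SKOV3 kb (FN1 -0.26, CD44 -0.70, LOXL2 -0.78), OVCAR8 inhibitors (PSKH1 0.27), kb between lines (PRKD2 0.30) and control lines (PRKD2 -0.38). With FPKM as deposited, log2 changes turned sign for OVCAR8 CRT (PRKD1 -0.10, PRKD3 -0.27), SKOV3 CRT (ANLN -0.40), SKOV3 kb (PRKD3 -0.76, FN1 -0.65, CD44 -1.29, LOXL2 -1.54), average (PRKD3 -0.17), OVCAR8 inhibitors (PRKD1 -0.18, PRKD2 -0.23, PRKD3 -0.59), kb between lines (PRKD3 -1.07) and control lines (PRKD1 -0.23). With voom, log2 changes turned sign for OVCAR8 CRT (PRKD1 -0.74), OVCAR8 kb (PRKD1 -2.96), SKOV3 CRT (ANLN -0.36, FKBP4 0.0043), SKOV3 kb (PRKD3 -0.11), average (PRKD1 -0.74), OVCAR8 inhibitors (PSKH1 0.050), SKOV3 inhibitors (RANBP2 -0.17), CRT between lines (LRCH3 0.58, PRKD2 0.014, PRKD3 -0.37) and kb between lines (PRKD1 2.2, PRKD3 -0.46). With SKOV3 fitted alone, log2 changes turned sign for average (CCN1 0.10, CCN2 0.35, STC2 0.42, BCL2L1 0.025). Leaving out 1 library turned signs, over ranges of log2 changes, for OVCAR8 CRT (PRKD1 -0.22 to 1.92, PRKD3 -0.051 to 1.58), OVCAR8 kb (PRKD1 -0.13 to 0.38), OVCAR8 inhibitors (PRKD1 -0.34 to 1.79, PRKD2 -0.14 to 1.02, PRKD3 -0.39 to 1.24), SKOV3 inhibitors (PRKD3 -0.13 to 0.75) and CRT between lines (PRKD1 -0.083 to 2.06, PRKD3 -0.44 to 1.19). With TPM the camera test, made on moderated t statistics, changed direction for lists in SKOV3 kb (cholesterol biosynthesis and uptake 0.059), OVCAR8 inhibitors (mesenchymal and invasion markers -0.049, unfolded protein response of the ER -0.030, NRF2 target genes -0.027, hypoxia and glycolysis 0.069, ribosomal protein genes 0.047, respiratory chain 0.0033) and SKOV3 inhibitors (mesenchymal and invasion markers 0.063, heat shock response 0.15), as relative means, which themselves stayed below 0 for the first 3 of OVCAR8. fry, which does not compare a list with other genes, had the opposite direction in OVCAR8 inhibitors (mesenchymal and invasion markers 0.19, unfolded protein response of the ER 0.036, NRF2 target genes 0.15, hypoxia and glycolysis 0.27), as means. Among named values called and tested again, 276 of 291 lost their call with TPM, 46 of 302 with FPKM as deposited, 62 of 303 with voom, 28 of 303 with a pseudocount of 0.1, 4 of 272 with TPM over median ratios, 50 of 303 with the replicate block, 66 of 221 with the line fitted alone, 6 of 30 with the named groups, 29 of 52 with OVCAR8, 15 of 52 with SKOV3 and 403 of 1708 over single omissions. Depth limits low genes in the SKOV3 inhibitor libraries and OVCAR8 CRT2, where 0 does not show absence.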

Other observations

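The count of splits that keep pairs of libraries was chosen after the other splits were seen. 14 of the 32 lists, Golgi trafficking and the MEF2 axis among them, in which PKD is known to act, passed camera in no comparison. In the average over inhibitors and lines, with members called, relative median and camera adjusted p, they were Golgi and post-Golgi trafficking (2 higher and 5 lower of 28, -0.40, adjusted p = 0.242), MEF2 and class IIa HDAC axis (0 higher and 1 lower of 14, -0.20, adjusted p = 0.857), Wnt/beta-catenin target genes (0 higher and 1 lower of 9, 0.18, adjusted p = 0.786), angiogenesis and growth factors (0 higher and 0 lower of 18, 0.05, adjusted p = 0.954) and aryl hydrocarbon receptor target genes (0 higher and 0 lower of 8, -0.28, adjusted p = 0.857). Growth, repair and immune lists gave autophagy and lysosome (1 higher and 1 lower of 28, -0.08, adjusted p = 0.979), epithelial markers (0 higher and 2 lower of 17, -0.22, adjusted p = 0.786), fatty acid synthesis (0 higher and 1 lower of 13, 0.04, adjusted p = 0.954), homologous recombination and DNA damage repair (0 higher and 1 lower of 23, -0.17, adjusted p = 0.875), interferon response (2 higher and 1 lower of 23, -0.06, adjusted p = 0.875), p53 target genes (1 higher and 0 lower of 16, -0.63, adjusted p = 0.155) and protein kinase D genes (0 higher and 1 lower of 3, 0.34, adjusted p = 0.878). Markers of other cell types gave fibroblast and stromal markers (1 higher and 0 lower of 11, 0.01, adjusted p = 0.801) and leukocyte and endothelial markers (3 higher and 2 lower of 10, 0.25, adjusted p = 0.707).

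Of 2025 ways to part the 6 libraries of each line into a control pair and 2 treated pairs, 100 were counted, and 1, the real one, gave as many genes in the average (3585, against at most 2990). Most of them part the libraries of a group, which puts group differences into the spread. Of the 9 that keep the pairs, 2, the real one included, gave as many, with 3648 in the other, and 9 cannot give a share under 0.05.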
